A study of Rattus norvegicus with 10 samples.

How the data were processed

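Circular RNA (circRNA) signal was measured in the submandibular gland, a salivary gland, of male rats aged 14 weeks. Spontaneously hypertensive rats (SHR) form one group and Wistar Kyoto rats (WKY) the control group, with 5 arrays each. The design text gives 5 rats per strain, and nothing in the labels ties an array to a rat beyond that, so p-values describe the spread between these arrays. Per the labels' protocols, total RNA was digested with RNase R, an exonuclease that degrades linear RNA, and the remaining RNA was amplified and labelled with Cy3 by random priming.

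Per the file headers, the spots were read with Agilent Feature Extraction 11.0.1.1 on arrays of 1 colour. The deposited scanner files give spot intensity on a linear scale, and the processed intensity had already been background-subtracted and spatially detrended by that program, per the file headers. The deposited marks of spots well above background, saturated or outlying were used as given. The authors' value table holds log2 values of the circRNA probes. Its ranks within each array equal those of median spot intensity minus median local background (Spearman's rho of 1 across probes, which are not independent replicates), and its medians lie between 7.34 and 7.37. The submitters' processing notes name limma. The normalization behind the table is not given in the sources used here.

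For the main values, log2 of the processed intensity was taken, spots of one probe were averaged, and the 75th percentile of each array over all non-control probes was subtracted. Control spots and spots marked as non-uniform or population outliers were left out. Probes well above background on at least 5 of the 10 arrays were kept; a probe with several spots counted as well above background where this held for at least as many of its spots as not. Of 14145 circRNA probes, 14099 were kept and 46 were not. With 79 other probes this gave 14178 tested probes. SHR was compared with WKY in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Log2 fold changes are SHR minus WKY. Principal components were taken from centred, unscaled values of the kept circRNAs, and mean scores of the strains were compared by an exact permutation test over all assignments of 5 of the 10 arrays. Plots were drawn with matplotlib 3.10.9.

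The arrays come from 3 scans, each taken here as 1 slide. The shared slide holds all 5 WKY arrays and 3 SHR arrays (SHR2-1, SHR2-3 and SHR3-1), the second slide holds SHR3-3 and the third slide, scanned on another day, holds SHR3-4. The strain comparison was therefore also made with slide as a block, which equals a comparison within the shared slide. On that slide strain nearly follows the row: row 1 holds 4 WKY arrays and row 2 holds WKY4-2 and the 3 SHR arrays, while SHR3-3 and SHR3-4 are in row 1 of their slides. The first number in the array names (2 and 3 in SHR, 1 and 4 in WKY) is not explained in the labels and was tried as a random block.

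The circRNA probes carry array identifiers that the sources used here do not pair with a host gene, a class or coordinates. The comparisons fixed for 14 lists of host genes, for circRNAs of one host gene and for circRNA classes were therefore not run. The rule fixed before the data were examined named the 8 circRNAs per direction with the largest changes among those that passed without overlap between strains, the 4 per direction with the smallest adjusted p, members of host gene lists and host genes with most changed circRNAs, and circRNAs detected in 1 strain only. Because identifiers without a gene say little, the list was shortened after the values were seen to the 2 circRNAs per direction with the smallest p. The arrays also hold 62 probes listed under transcript records, with 10 spots each. For 39 of them, 38 gene symbols were found in a table of the GRCr8 assembly, which was used for names only; 37 probes of 36 genes were kept. None of these symbols is in the 14 lists, and their comparison was chosen after the files were read. Another 20 custom probes, with 20 spots each, have no annotation in the files.

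Alternatives fixed beforehand were quantile normalization, the 75th percentile over probes detected on all arrays, the median in place of that percentile, normexp background correction with an offset of 50 followed by quantile normalization, no filter, a filter requiring all 10 arrays, the authors' value table, an intensity trend with robust variance, array weights, slide as a block, the first name number as a random block, leaving out each array, and thresholds of unadjusted p with a fold of 1.5 or 2. The scanner files give no mean spot intensity column, so normexp used the median. Chosen after seeing the data were the row of the array on its slide as a block, slide and row together as blocks, the interquartile range of each array as a covariate, the 8 arrays of the shared slide alone, the authors' value table without a filter, and the first 1, 2 and 3 principal components of the within-strain residuals as covariates. The residual components were tried first, and the interquartile range was picked after their result and the first principal component had been seen.

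The test was checked on 10 simulated comparisons of 5 against 5 arrays that kept the covariance of 13954 circRNAs, with 200 of them changed. It recovered on average 11.2% of circRNAs changed 1.5-fold, 35.1% of those changed 2-fold and 86.4% of those changed 4-fold. Single runs ranged over 0 to 55%, 6 to 75% and 65 to 97%. The averages include a run with many false calls, and both groups were simulated with the same spread. The median number of false calls was 0, but 1 of the 10 runs gave 5515, so shared variation between arrays can by chance line up with the groups and yield many false calls. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.28.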

Results

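The arrays profiled circRNAs, RNAs closed into a ring by back-splicing, in the submandibular gland of SHR and WKY. SHR is an inbred strain that develops high blood pressure, and WKY is the normotensive control strain. There were 5 arrays per strain. Nearly all probes gave signal: 13615 of 14145 circRNA probes were well above background on all 10 arrays, and between 97.4% (SHR3-4) and 99.9% were so on each array. Median circRNA signal after background subtraction ranged from 65.4 (WKY4-2) to 162 (WKY4-1) intensity units, where negative control spots had medians of 1.02 to 2.76. The median local background, which is not on this subtracted scale, was 15 to 18, and 0 non-control spots were saturated.

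The first question was whether strain was the main difference between the glands' circRNA profiles. It was not. The first principal component held 55.1% of the variance and the second 18.7%, and both strains lay across the first. Mean first-component scores were -10.3 ± 62.4 (SD, n = 5) in SHR and 10.3 ± 36.9 (SD, n = 5) in WKY. The exact permutation test (two-sided, over all assignments of 5 of the 10 arrays, smallest possible p 0.00794) gave p = 0.540 for the first component, 0.325 for the second and 0.349 for the third, or 0.540, 0.524 and 0.524 after Benjamini-Hochberg adjustment over the 3. Over the 8 arrays of the shared slide the exact permutation p for the first component was 0.679. Correlations across circRNAs, which are not independent replicates, had a median of 0.911 between arrays of one strain and 0.914 between strains. Only 2 of the 10 arrays were most similar to another array of their own strain.

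**Figure D1:**
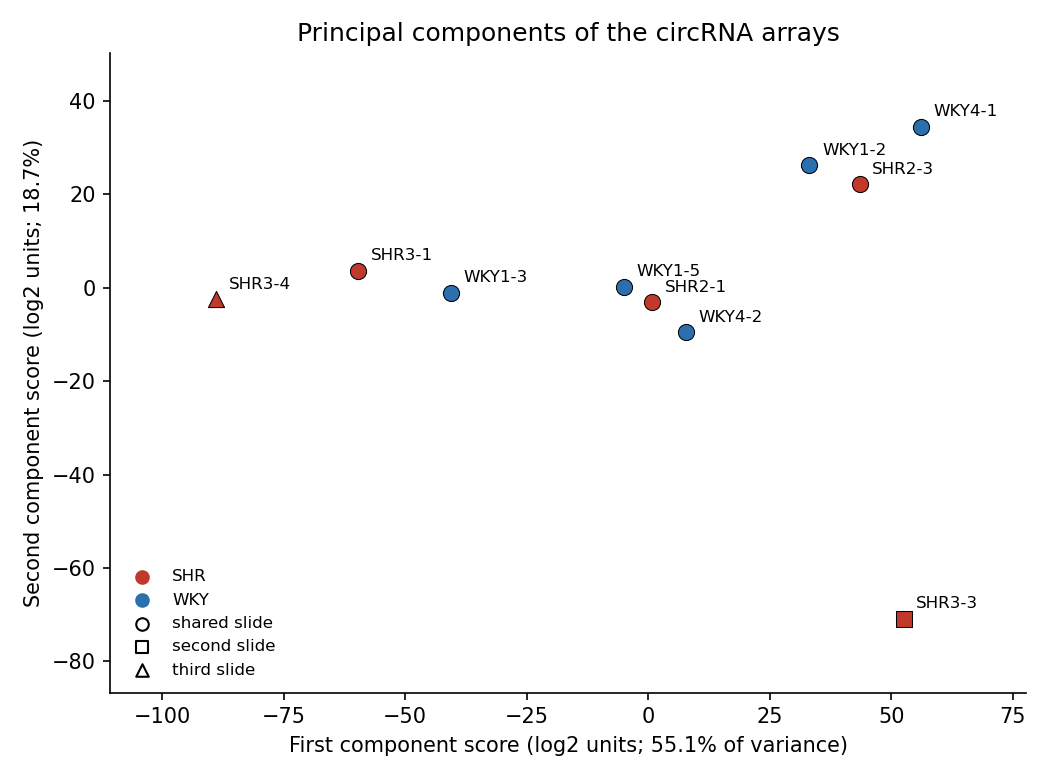
First component score (x axis) against second component score (y axis), both in log2 units, for the 10 arrays; colour gives the strain and the marker the slide. Scores of both strains overlap on the first axis, and SHR3-3 lies apart on the second at -70.9.

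The second question was which circRNAs differed between SHR and WKY. Against this shared background a small set stood out: 13 of 14099 circRNAs passed the test, 9 higher in SHR by 2.28- to 4.04-fold and 4 lower in SHR by 2.35- to 4.55-fold. ASCRPR005960 rose, with a log2 signal relative to the array's 75th percentile of 4.45 ± 0.21 (SD, n = 5) in SHR and 2.43 ± 0.33 (SD, n = 5) in WKY, a 4.04-fold difference (95% interval 2.94 to 5.57). ASCRPR010484, among the brighter circRNAs, was at 5.88 ± 0.20 in SHR and 4.06 ± 0.25 in WKY (SD, n = 5 each), which is 3.53-fold (2.64 to 4.74). ASCRPR006399 fell from -0.60 ± 0.18 in WKY to -2.65 ± 0.24 in SHR (SD, n = 5 each), so that it was 4.12-fold (3.10 to 5.49) higher in WKY; the size of this change depended on the processing, with a log2 fold change of -0.97 with normexp and -0.87 in the authors' value table, against -2.04 here. ASCRPR000911 fell from 2.58 ± 0.35 in WKY to 0.39 ± 0.43 in SHR (SD, n = 5 each), 4.55-fold (3.10 to 6.68).

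The log2 fold changes were 2.02 (SE 0.21) for ASCRPR005960, 1.82 (SE 0.19) for ASCRPR010484, -2.04 (SE 0.19) for ASCRPR006399 and -2.19 (SE 0.25) for ASCRPR000911. Their adjusted p-values in limma were 0.00230, 0.00230, 0.00220 and 0.00371. For each of the 13 circRNAs all 5 SHR arrays lay on one side of all 5 WKY arrays, and all 13 were well above background on 10 arrays. Such separation was seen for 166 of the 13908 circRNAs measured on all arrays, or 1.19%, where chance gives 0.794% on average. Because circRNAs of one array are not independent, the share can lie far from that average by chance, and the difference was not tested. Adjusted p-values of the 13 ran up to 0.0387, and the next circRNA had 0.0644. The sources used here do not pair these identifiers with host genes. The lowest adjusted p of ASCRPR010484 over the alternatives was 2.13e-05, with the first 3 residual components as covariates, in which the error is understated. It missed the threshold with quantile normalization (adjusted p = 0.0550), normexp (0.0926), the authors' value table (0.0785, or 0.0801 without a filter) and the intensity trend with robust variance (0.168). Its log2 fold change was no smaller in these, at 2.22, 2.10, 2.27 and 1.82, but it was 1.60 with slide and row together as blocks, where it missed too (adjusted p = 1.00).

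**Figure D2:**
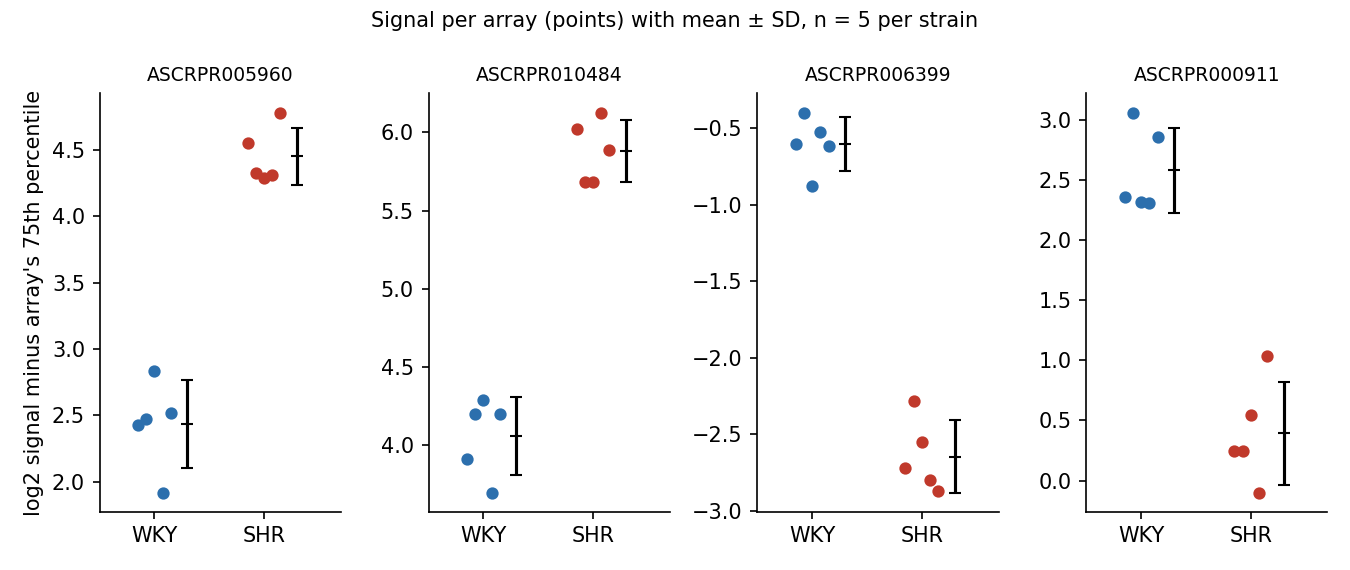
Log2 signal minus the array's 75th percentile (y axis) of 4 circRNAs in WKY and SHR; points are arrays, and bars give the mean ± SD, n = 5 per strain. The strains do not overlap in any panel.

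No other circRNA passed the test. At an unadjusted p under 0.05 there were 489 circRNAs, or 3.47%, where 705 are expected on average with no difference. That average is a poor guide, because circRNAs of one array are not independent. Other splits of the arrays into equal groups gave from 12 to 6295 such circRNAs. The count of 489 lay within this range and above most of these splits, so it does not decide whether the strains differ. Of the 489 circRNAs, 128 were higher and 199 lower in SHR with a fold of at least 1.5. With a fold of at least 2, 27 were higher and 52 lower. In the authors' value table the same limits gave 45 higher and 48 lower, and 15 higher and 11 lower. The median 95% interval of a log2 fold change reached 0.62 to either side. No circRNA was well above background on every array of one strain and on none of the other (0 in each direction).

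**Figure D3:**
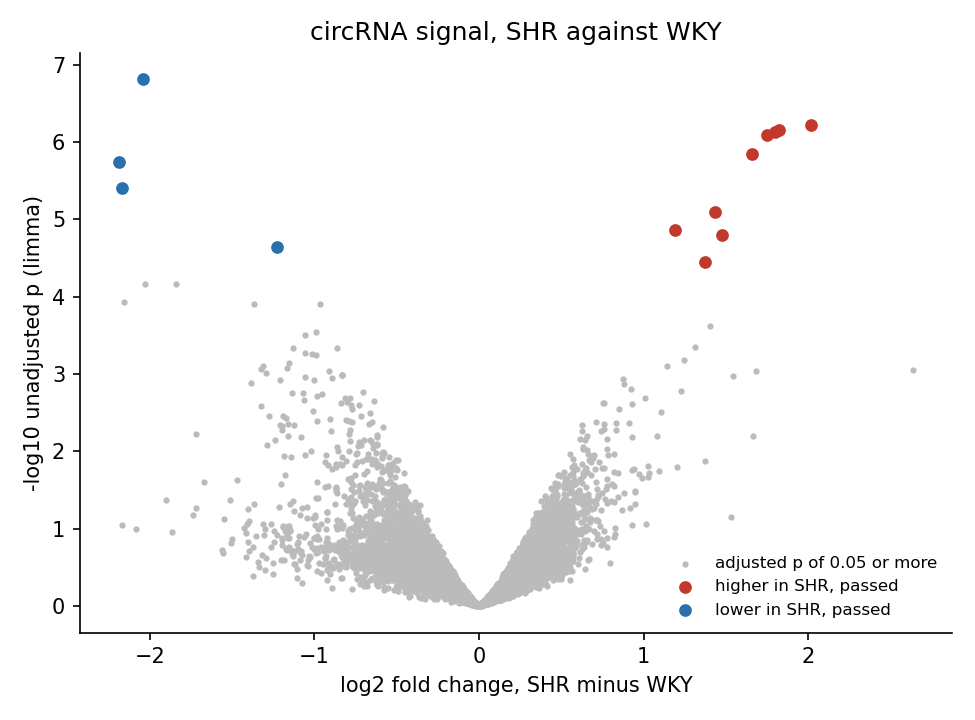
Log2 fold change, SHR minus WKY (x axis), against -log10 of the unadjusted limma p (y axis) for 14099 circRNAs; coloured points passed at an adjusted p under 0.05. The coloured points are the 9 circRNAs higher and the 4 lower in SHR, and the next circRNA had an adjusted p of 0.0644.

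Within the shared slide, 3 SHR against 5 WKY arrays, 13 circRNAs also passed, 8 higher and 5 lower. These included 11 of the 13, and all 13 kept their direction. Since the strains did not overlap for any of the 13, their direction could not change here or with blocks for slide or row. With the row on the slide as a block 9 of the 13 passed, and 4 lost their call (adjusted p 0.0858 to 0.118). With slide and row together as blocks 0 passed (adjusted p of the 13 from 0.608 to 1.00), because this fit sets 3 SHR arrays against WKY4-2 alone; all 13 kept their direction, the median size of their log2 fold changes was 93.6% of that without blocks, and their median SE was 0.34 against 0.19. The count depended on the processing: 104 circRNAs (33 higher, 71 lower) passed with array weights, 7 (4 higher) with an intensity trend and robust variance, 21 (11 lower) with the first name number as a random block and 42 (15 higher, 27 lower) with the interquartile range as a covariate. Directions were 7 higher and 6 lower after quantile normalization alone, and 3 higher and 6 lower with normexp and in the authors' value table, which differ from the main values in background correction too. The count fell to 8, with 5 higher, without SHR2-1, SHR3-1, WKY1-2, WKY1-3, WKY4-1 or WKY4-2, and 8 were lower without SHR3-3.

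The third comparison used the probes listed under mRNA records, which show what remained of 36 named transcripts after RNase R digestion; a probe of this kind can also bind a circRNA that holds the same exon. None was found to change: 0 of 37 probes passed in limma, both over all probes and adjusted over the list alone (smallest adjusted p 0.885), and over all arrays 1 had an unadjusted p under 0.05. That was Hsp90ab1, a cytosolic chaperone, with a log2 fold change of 0.64 (95% interval 0.02 to 1.27, unadjusted p = 0.0441 in limma), which was 0.37 within the shared slide (unadjusted p = 0.113) and 0.39 without SHR3-4. B2m, the light chain of MHC class I, had -0.89 (-1.90 to 0.11), from 1.00 ± 1.15 in SHR and 1.90 ± 0.31 in WKY (SD, n = 5 each). Its value was -0.71 within the shared slide (unadjusted p = 0.0451 in limma) and -0.47 without SHR3-3. B2m passed, at an adjusted p of 0.0357 and 0.0226, with the first 2 and 3 residual components as covariates, in which the error is understated; its range over alternatives was 0.0226 to 1.00. Trim2, a ubiquitin ligase, had 0.52 (-0.02 to 1.06), which was 0.25 within the shared slide and 0.32 without SHR3-4.

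Apart from Hsp90ab1, none of the 37 probes had an interval that excluded 0. Actb, a cytoskeletal actin, had 0.15 (-0.34 to 0.64), and Sdha, a subunit of succinate dehydrogenase, had 0.08 (-0.46 to 0.62). The ribosomal protein genes Rplp1 and Rpl13a had 0.07 (-0.47 to 0.62) and 0.38 (-0.22 to 0.98). Values were -0.19 (-0.94 to 0.56) for Gusb, a lysosomal glucuronidase, and -0.14 (-0.95 to 0.67) for Hprt1, an enzyme of purine salvage. The glycolytic genes Pgk1 and Ldha had -0.03 (-0.99 to 0.94) and, for the 2 Ldha probes, 0.41 (-0.21 to 1.04) and -0.01 (-1.07 to 1.04). The first of these was 0.31 within the shared slide, 0.17 without SHR3-4 and -0.16 with slide and row together as blocks.

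Ndfip1 and Ndfip2, adaptors of Nedd4-family ubiquitin ligases, had 0.31 (-0.43 to 1.05) and 0.33 (-0.47 to 1.13). Without SHR3-4 they were 0.01 and 0.14, without SHR3-3 0.56 and 0.67, and within the shared slide 0.23 and 0.53. The growth factor genes Fgf2 and Gdnf had -0.21 (-1.03 to 0.60) and -0.06 (-0.96 to 0.83). Fgf2 was -0.01 without SHR3-4 and -0.51 without SHR3-3. Ptk2b, a calcium-sensitive tyrosine kinase, had 0.36 (-0.41 to 1.13), P2rx2, an ATP-gated channel, 0.13 (-0.69 to 0.95), and Nlrp3, an inflammasome sensor, -0.12 (-1.02 to 0.77). Pld1, a phospholipase D gene, had 0.11 (-0.69 to 0.91) over all arrays and 0.58 (unadjusted p = 0.0166 in limma) within the shared slide, and was well above background on only 7 arrays. Enpp1, an ectonucleotidase, had 0.35 (-0.24 to 0.94), or 0.06 within the shared slide and 0.10 without SHR3-3. Slc28a2, a nucleoside transporter, had -0.24 (-0.96 to 0.48), or -0.04 without SHR3-4 and -0.42 without SHR3-3. Fitted values were above 0 for 19 probes and below 0 for 18, and 22 of the 37 intervals lay within 1 log2 unit of 0. Within the shared slide 30 of the 37 values kept their sign, among them Ptk2b at 0.10, Rpl13a at 0.18 and Gdnf at -0.38, and 17 changed sign without one of the arrays. These genes were chosen after their values were seen.

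**Figure D4:**
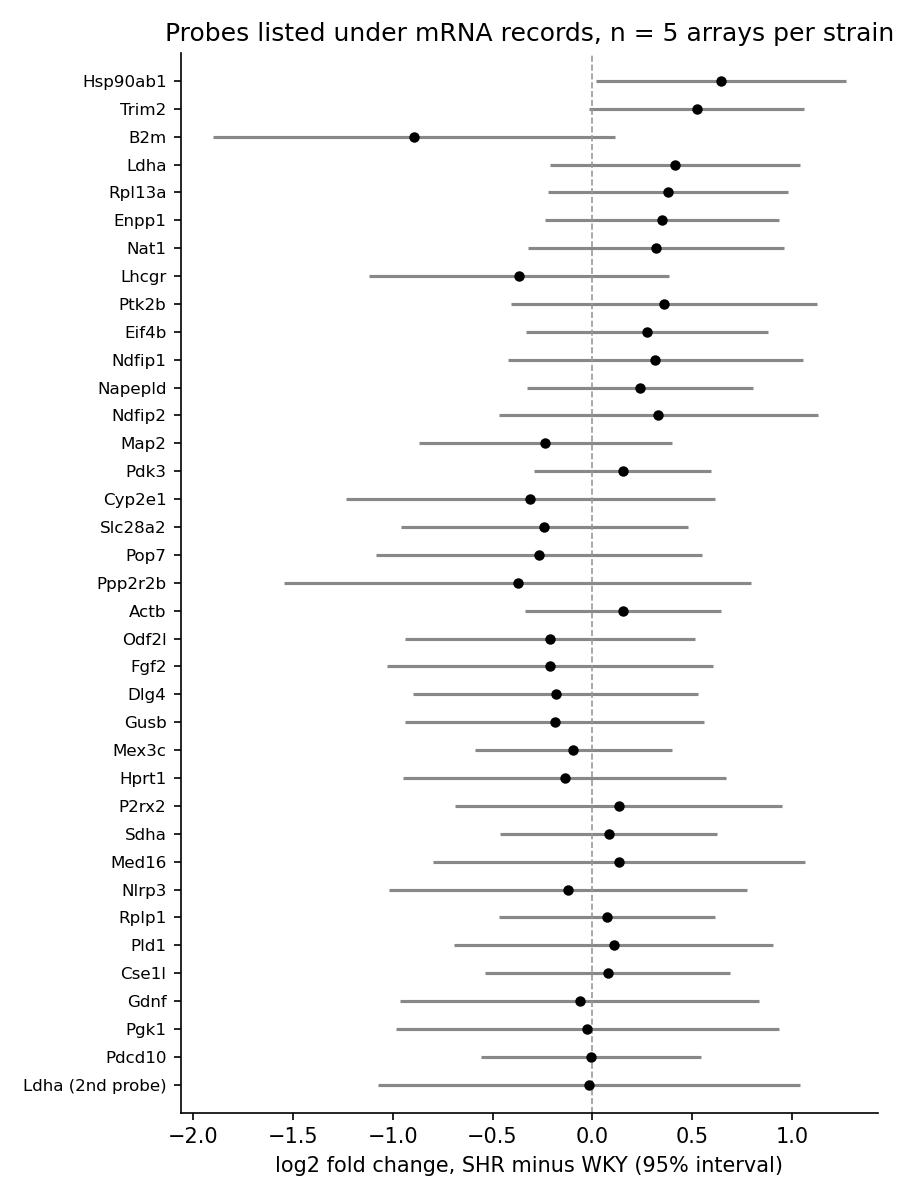
Log2 fold change, SHR minus WKY, with its 95% interval (x axis) for 37 probes of 36 genes (y axis), n = 5 arrays per strain, in order of unadjusted p. Only the interval of Hsp90ab1 excludes 0, and no probe passed after adjustment.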

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

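Of the tests in this part, those of the slide, the spread of signal and the sample labels were chosen after their result or related values had been seen. So was the fit with slide and row together. The block for the row on the slide was added after seeing the data, but what it would show was written down before its result, as for the count of other splits.

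The first pattern is the set of 13 circRNAs that passed. Of 100 splits of the 10 arrays into 5 against 5, drawn from 126 with the real one included, 3 gave as many circRNAs. That is under the share of 0.05 written down beforehand, with a real count of 13 and 4040 as the highest other. Chance is still not excluded, because the splits do not keep slide and row. Moreover, 1 of 10 simulated comparisons, whose shared variation was drawn without regard to strain, gave 5515 false calls, although the next highest gave 3. The split with 4040 and one with 2460 separated the arrays by first-component score more than any other split drawn, which points to a structure of the samples. Their mean differences were 77.3 and 74.5, where the strains differed by -20.6 (SHR minus WKY). The other 97 splits gave 0. Within the shared slide the median size of the log2 fold change of the 13 was 99.3% of that over all arrays. With the row on the slide as a block, where 9 of the 13 passed, it was 99.2%. Both values argue against slide or row by itself as the whole cause, although all these arrays took part in choosing the 13. Slide and row together stay open, because with both as blocks the 3 SHR arrays of the shared slide stand against WKY4-2 alone. The median size was then 93.6% of that without blocks, with a median SE of 0.34 against 0.19. A strain difference is a candidate explanation that stays a hypothesis. A sequence variant between the strains under a probe, the origin of the animals and their handling were not tested. Nor was a variant at a splice site, which would itself be a strain difference.

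The second pattern is the first axis, which separates arrays within both strains. Scores varied over the 8 arrays of the shared slide with 0.810 of the SD over all 10, which argues against the slide, and 0 of 10 arrays lay nearer the other strain over the 20 circRNAs with the smallest p chosen without that array, which argues against a mislabelled sample. The score followed the interquartile range of each array's log2 values (r = -0.946, permutation p = 2e-05, and rho = -0.976, p = 1e-05, the smallest the permutations can give). Adjusted over 3 relations these p-values were 6e-05 and 3e-05. Without SHR3-3 and SHR3-4, the 2 arrays farthest from the median range, r was -0.989. Since these are also the 2 arrays off the shared slide, the value within that slide is the same calculation. Score and range come from the same values, so a relation can arise by construction, and these p-values do not bear on a cause. Removing a straight line of each array on the mean profile took away 35.4% of the axis's variance, between the limits set for and against the spread of signal as the cause, so that explanation stays open, as does RNA quality, which was not tested. The other relations were r = 0.360 (p = 0.31, adjusted 0.46; rho = 0.248, p = 0.49, adjusted 0.74; r = 0.211 without 2 arrays; 0.593 within the shared slide) with median signal and r = 0.0156 (p = 0.97, adjusted 0.97; rho = -0.00617, p = 0.99, adjusted 0.99; r = -0.523 without 2 arrays; 0.128 within the shared slide) with local background.

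Single arrays far from the other 4 of their strain were found in 5 of 90 groups tested, where chance gives about 4.5. SHR3-4 had Hsp90ab1 at 4.96 on the log2 scale relative to the 75th percentile, against 3.58 to 3.72 in the other SHR arrays, a gap of 0.899 of the range. SHR3-4 also had Pld1, a phospholipase D gene, at -5.97 against -4.33 to -3.70 (0.722 of the range); this dim probe was well above background on 7 arrays and not on SHR3-4, so the distance is not exact. SHR3-3 had Enpp1 at -2.18 against -3.60 to -3.27 (0.770), and a second-component score of -70.9 against -3.13 to 22.1 (0.728). WKY4-2 had one Ldha probe at 0.67 against -0.08 to 0.13 (0.717).

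Of the 20 custom probes with no annotation, 13 were well above background on all 10 arrays. Their median intensity per array was 14.8 to 53.6, where negative control spots had 1.02 to 2.76. All 20 were tested between the strains in limma: 0 passed and 0 had an unadjusted p under 0.05.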

How the results depend on the processing

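The slide row, slide and row together, the interquartile range, the 8 arrays alone, the residual components, the unfiltered authors' table and all tests of mRNA probes were chosen after seeing the data.

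All 13 circRNAs kept their direction under the 21 alternatives that give fold changes of their own, and 8 more repeat those of another fit. Leaving out arrays, the shared slide, array weights and slide or row blocks could not change it, since the strains never overlapped in these 13. Counting the shared slide once and without the residual components, 0 to 13 of them passed under 25 alternatives. ASCRPR005960, ASCRPR006399 and ASCRPR000911 passed under 24 of these, and ASCRPR010484 under 19. With slide and row together as blocks 0 circRNAs passed, 0 higher and 0 lower, since 1 WKY array, assumed to vary like the others, then stands against 3 SHR arrays; with the row alone 9 passed (6 and 3). Counts of changed circRNAs (13, with 9 higher and 4 lower) were 7 with 4 higher under an intensity trend with robust variance, 104 (33 and 71) with array weights, and 21 with 11 lower with the first name number as a random block, whose estimated correlation was -0.157. They were 42 (15 and 27) with the interquartile range as a covariate. With normexp, and in the authors' value table with or without a filter, 3 were higher. Unadjusted thresholds gave 327 (128 and 199) at a fold of 1.5 and 79 (27 and 52) at a fold of 2. Causes of the other changes were not tested, apart from the looser thresholds.

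With the first 1, 2 and 3 components of the within-strain residuals as covariates, counts were 46 (18 and 28), 501 (120 and 381) and 1112 (307 and 805), and 0, 1 and 1 mRNA probes passed adjusted over the list alone. These are not relied on: components taken from a fit's own residuals shrink the error it is tested against.

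Leaving out each array gave 8 to 16 circRNAs, 5 to 8 higher and 3 to 8 lower. The count was 8, with 5 higher, without SHR2-1, SHR3-1, WKY1-2, WKY1-3, WKY4-1 or WKY4-2, and 8 were lower without SHR3-3; fewer arrays were then tested. The first component did not separate the strains under any of 19 alternatives (exact permutation p 0.270 to 0.937), and 0 mRNA probes passed under the other 25.

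No paired analysis was possible because the strains share no replicate numbers. Host gene lists, circRNAs of one host gene and circRNA classes were not run, for want of host genes and classes. Few probes are limited by signal over background: 46 circRNAs were too dim to test.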

Other observations

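The tests in this part were all chosen after related values had been seen.

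Arrays differed more within SHR than within WKY. The SHR arrays lie on 3 slides and all 5 WKY arrays on the shared slide, so over all arrays strain and slide cannot be told apart in this. The median SD of a circRNA was 0.54 in SHR and 0.33 in WKY, and 11168 of 13908 circRNAs varied more in SHR. For the mRNA probes, among them B2m and Actb, the medians were 0.72 and 0.37, and 33 of 37 varied more in SHR. On the shared slide, with 3 SHR arrays, the SHR medians were 0.38 and 0.52, and 8270 circRNAs and 25 mRNA probes varied more in SHR than in the 5 WKY arrays. The difference in spread was not tested, since probes of one array are not independent.

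The 9 circRNAs higher in SHR, ASCRPR005960 and ASCRPR010484 among them, may be probes that read one RNA or RNAs that rise together. Their within-strain residuals had a median pairwise correlation of 0.371, against a median of 0.024 in 10000 random lists matched on signal. This was above 88.5% of the lists and short of the limit set for a higher correlation than in such lists, so the hypothesis is left open.

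Linear RNA left after digestion could be a source of the first axis. The median slope of the mRNA probes on the standardized first-component score was 0.20, against 0.28 for random circRNA lists matched on signal, above 20.7% of them. That lies between the limits set for and against the hypothesis, and linear RNA cannot be told apart here from a change shared by all probes of like signal.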
